A study of Homo sapiens with 6 samples.

How the data were processed

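RNA-seq of ACHN cells covered 6 libraries, 3 transfected with a control siRNA and 3 with an siRNA against OTUD1. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a NEBNext Ultra Directional kit, which keeps the strand of the RNA. The submitters' processing notes name the genome build hg38. The aligner, the counting tool, its strand setting, the annotation and any selection of RNA before library preparation are not given in the sources used here. Since the strand setting is not given, antisense genes and genes that overlap on opposite strands (among them HMGA2, EMC10, KRT8 with KRT18, and FAS with ACTA2) carry uncertain counts.

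The deposited table holds 1 value per gene symbol and library. Its name speaks of FPKM, but the deposited values are whole-number counts whose totals differ between libraries, and they were treated as raw counts. The plan written before the data were examined had assumed FPKM and limma on a log scale. Because the unit is counts, edgeR's quasi-likelihood test took its place as the main test. The table has 58735 rows, of which 30560 have no count in any library, and no row lacks a gene name. Symbols matched GENCODE 29 for 99.95% of rows. Another row shares the symbol in 1745 rows, and 27 rows have symbols altered to look like dates, 20 of them among the genes tested. Neither kind was named among the largest changes. Coordinates and gene types come from GENCODE 29, which uses the same build.

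Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (at least 10 counts at the median library size in 3 libraries and 15 in all), which left 15244, and scaled by TMM. Levels are given as CPM, counts relative to the scaled library size. Normalization factors were 0.9549 to 0.9572 for the control libraries and 1.045 to 1.046 for the OTUD1 siRNA libraries. The 2 groups were compared with glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The SE of a log2 fold change was taken from the fold change and its F statistic. The biological coefficient of variation was 3.8%. Gene lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 between genes, again with a correlation estimated per list, and with fry, and adjusted over the 22 lists.

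The 22 gene lists were fixed before the data were examined, as was the rule for named genes. It took OTUD1, STAT3 and CD274, the 8 largest increases and 8 largest decreases among called genes whose groups did not overlap, up to 4 called members of each list with the smallest adjusted p, and up to 2 called members that moved against most of their list. It left out symbols starting LOC or LINC, with a dot or an Ensembl identifier, antisense and divergent transcripts, pseudogene names ending in P plus a number, XIST and Y-linked genes. Pseudogenes were first recognised by the ending of the symbol, which wrongly dropped IGFBP3 and BMP2. This was corrected to the annotated gene type after the values had been seen, to follow the rule as written. Some genes that the rule takes are not reported here.

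Total counts were 16753495, 18993534 and 17921233 in control replicates 1 to 3 and 21013530, 19276411 and 17243433 in OTUD1 siRNA replicates 1 to 3. A count of 3 corresponds to 0.137 to 0.188 CPM, depending on the library. For genes with at most 30 counts in a group, folds come from summed counts, with 95% intervals from the exact binomial method, and a group at 0 was set to a floor of 3 counts over the group. These intervals and floors cover counting error only. Libraries of the same group differed by more than sampling noise (mean chi-square per gene 2.11 to 4.07, against 53.7 to 63.6 between groups), so no library was counted as a copy of another. The fit was tested on simulated data with 200 changed genes for the comparison of OTUD1 siRNA with control siRNA. Over 15159 genes, it recovered 79.8% of tested genes changed by 0.5 and 91.8% of those changed by 1 on the log2 scale, with 13 false calls. The simulated changes went up and down equally, and all genes shared the same dispersion. The simulation therefore does not test the scaling, or the rate of false calls where as many genes change as in these data.

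Alternatives covered the filter on low counts, the scaling (DESeq-type size factors, quantile normalization, library totals), the tool (DESeq2 1.42.0 and limma), the dispersion estimate, the replicate number as a block, each replicate left out in turn, and the kind of set test. For the closing section, 3′ UTRs of at least 50 bases, from the annotated principal transcript of each of 12409 tested genes (the longest where several qualified), were searched for all 7-mers. The log2 fold change was regressed on the presence of each 7-mer with 3′ UTR length and GC content as covariates (Python 3.11.15, numpy 2.4.6, scipy 1.17.1). The sequence of the OTUD1 siRNA is not given in the sources used here, and no siRNA sequence was used.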

Results

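RNA was sequenced from ACHN cells, a human renal cancer cell line, after transfection with a small interfering RNA (siRNA) against OTUD1 or with a control siRNA. OTUD1 is a deubiquitinase of the OTU family, an enzyme that removes ubiquitin from other proteins. Each group held 3 libraries. Total counts per library ranged from 16753495 to 18993534 in the control group and from 17243433 to 21013530 in the OTUD1 siRNA group, and 15244 genes had enough counts to be tested. The labels do not say that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Values are TMM-scaled CPM, as mean ± SD of 3 libraries, and log2 fold changes are OTUD1 siRNA over control siRNA with their standard error (SE).

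The first question was whether the siRNA lowered OTUD1 mRNA and how the mRNAs of STAT3 and CD274, which the study's title names, moved with it. OTUD1 mRNA was 3.22-fold lower after OTUD1 siRNA, and STAT3 mRNA was 1.34-fold higher. CD274, which encodes the T-cell checkpoint ligand PD-L1, had a mean 1.17-fold above control but did not pass the test. STAT3 encodes a transcription factor activated downstream of cytokine receptors.

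OTUD1 (ENSG00000165312.6; hg38 chromosome 10, 23439458 to 23442390, plus strand, a gene without introns in GENCODE 29) was at 3.77 ± 0.0684 CPM in the control libraries and 1.17 ± 0.288 CPM in the OTUD1 siRNA libraries. Its log2 fold change was -1.69 (SE 0.24, edgeR quasi-likelihood adjusted p = 4.37e-07), and it was lower in 3 of 3 libraries. These levels rest on 61 to 67 counts per control library and 17 to 28 counts per OTUD1 siRNA library. STAT3 (ENSG00000168610.14; chromosome 17, 42313324 to 42388568, minus strand) rose from 181 ± 3.53 to 242 ± 1.82 CPM, a log2 fold change of 0.42 (SE 0.034, edgeR adjusted p = 7.83e-12), and all 3 OTUD1 siRNA libraries lay above all 3 control libraries. CD274 (ENSG00000120217.13; chromosome 9, 5450503 to 5470566, plus strand) was at 9.74 ± 0.72 CPM in the control group and 11.4 ± 1.03 CPM in the OTUD1 siRNA group. Its log2 fold change was 0.22 (SE 0.11, edgeR adjusted p = 0.0797), and the values of the 2 groups overlapped. Without OTUD1 siRNA replicate 3 the CD274 log2 fold change was 0.29 and its adjusted p 0.0373, while over all the other settings tried the adjusted p ran from 0.00632 to 0.246.

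**Figure D1:**
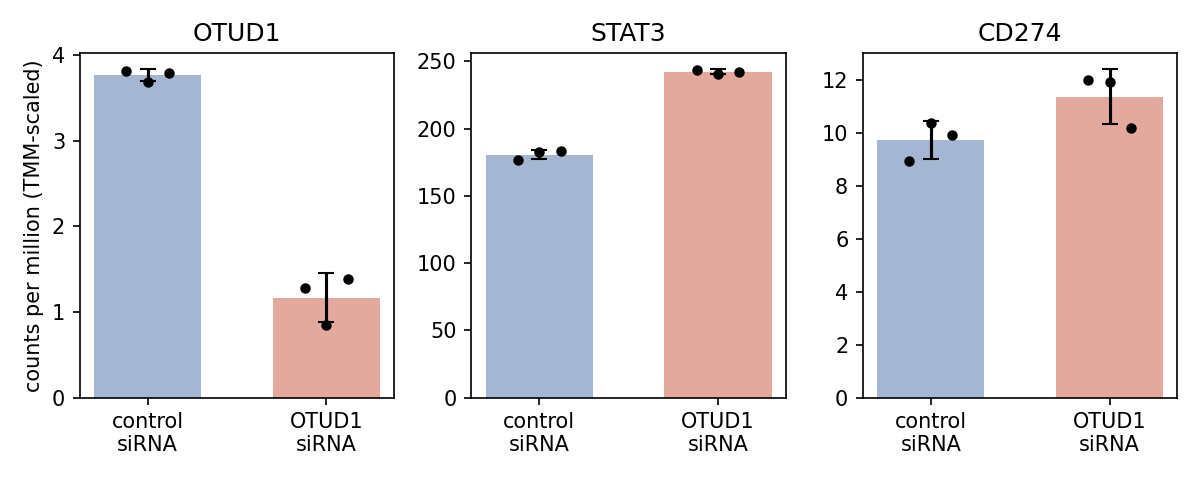
TMM-scaled CPM (vertical axes, from 0) of OTUD1, STAT3 and CD274 in the 3 control siRNA and 3 OTUD1 siRNA libraries; bars are group means, error bars SD and points single libraries. OTUD1 fell from a mean of 3.77 to 1.17 and STAT3 rose from 181 to 242, with no overlap between the groups, while the CD274 values of the 2 groups overlapped.

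Across the transcriptome, IGFBP3, which encodes a secreted binding protein of insulin-like growth factors, rose 9.3-fold, while EMC10, a subunit of the endoplasmic reticulum membrane complex, fell 6.24-fold. HMGA2, an architectural chromatin protein, fell 5.65-fold, the collagen-binding integrin subunit ITGA2 fell 4.99-fold, AMMECR1 fell 4.95-fold and the cell-cycle regulator CCND1 (cyclin D1) fell 4.54-fold. Of the 15244 genes tested, 4460 were higher and 4746 lower after OTUD1 siRNA, together 60.4%. A change of at least 1 on the log2 scale was seen for 844 higher and 538 lower genes, and the median size of the called changes was 0.47 on the log2 scale. With limma after quantile normalization, the genes changed by at least 1 numbered 225 higher and 298 lower, and with a minimum mean of 5 CPM 254 and 282.

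IGFBP3 went from 42.1 ± 2.53 to 392 ± 10.4 CPM (log2 fold change 3.22, SE 0.043, edgeR adjusted p = 1.65e-29). The other genes with the largest increases had few counts in the control libraries. KRTAP2-4, a keratin-associated protein gene, had 0 counts in all 3 control libraries and 148 counts over the OTUD1 siRNA libraries, at least 42.1-fold higher against a floor of 3 counts over the group. Its neighbour and close relative KRTAP2-3 rose 13.1-fold (SE 0.2 on the log2 scale), and reads of the pair may be split between them, so both values are uncertain. PSG4, from a family of near-identical pregnancy-specific glycoprotein genes and therefore also uncertain, was 10.4-fold higher with a 95% counting interval of 5.3 to 23.4. The long non-coding RNA LOH12CR2, with 3 control counts in all, was 11.4-fold higher (interval 3.62 to 57.5). AANAT, an enzyme of melatonin synthesis, was 8.17-fold higher (3.75 to 21.1), ADPRHL1 6.42-fold (4.06 to 10.7) and ZAR1 6.37-fold (3.7 to 11.8).

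Among the decreases, EMC10 went from 147 ± 2.97 to 23.5 ± 0.433 CPM (log2 fold change -2.64, SE 0.049, edgeR adjusted p = 2.33e-26) and HMGA2 from 463 ± 10.7 to 81.8 ± 3.25 CPM (-2.5, SE 0.037, adjusted p = 7.41e-29). ITGA2 had a log2 fold change of -2.32 (SE 0.1), AMMECR1 of -2.31 (SE 0.077) and the keratin gene KRT2 of -2.58 (SE 0.25). BMP2, a secreted growth factor, was 8.9-fold lower (95% counting interval 3.5 to 29) from 38 counts over the control libraries and 5 over the OTUD1 siRNA libraries. MIR200B, with 47 and 3 counts, was 18.4-fold lower (5.91 to 92.2), and MIR3648-1 fell 5.73-fold. Both are short microRNA genes, whose counts in these libraries need not reflect the mature microRNA. The 3′ UTRs of BMP2, HMGA2, ITGA2, AMMECR1 and EMC10 carry the 7-mer CAAACAA, which also occurs in the OTUD1 mRNA. That of KRT2 does not, and the microRNA genes have no 3′ UTR to search. Of the 12409 genes with a 3′ UTR searched, 1742 carry CAAACAA. The 3′ UTR of BMP2 is 1191 bases long and those of HMGA2, ITGA2, AMMECR1 and EMC10 are 3003 to 8611. Length was not allowed for here.

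**Figure D2:**
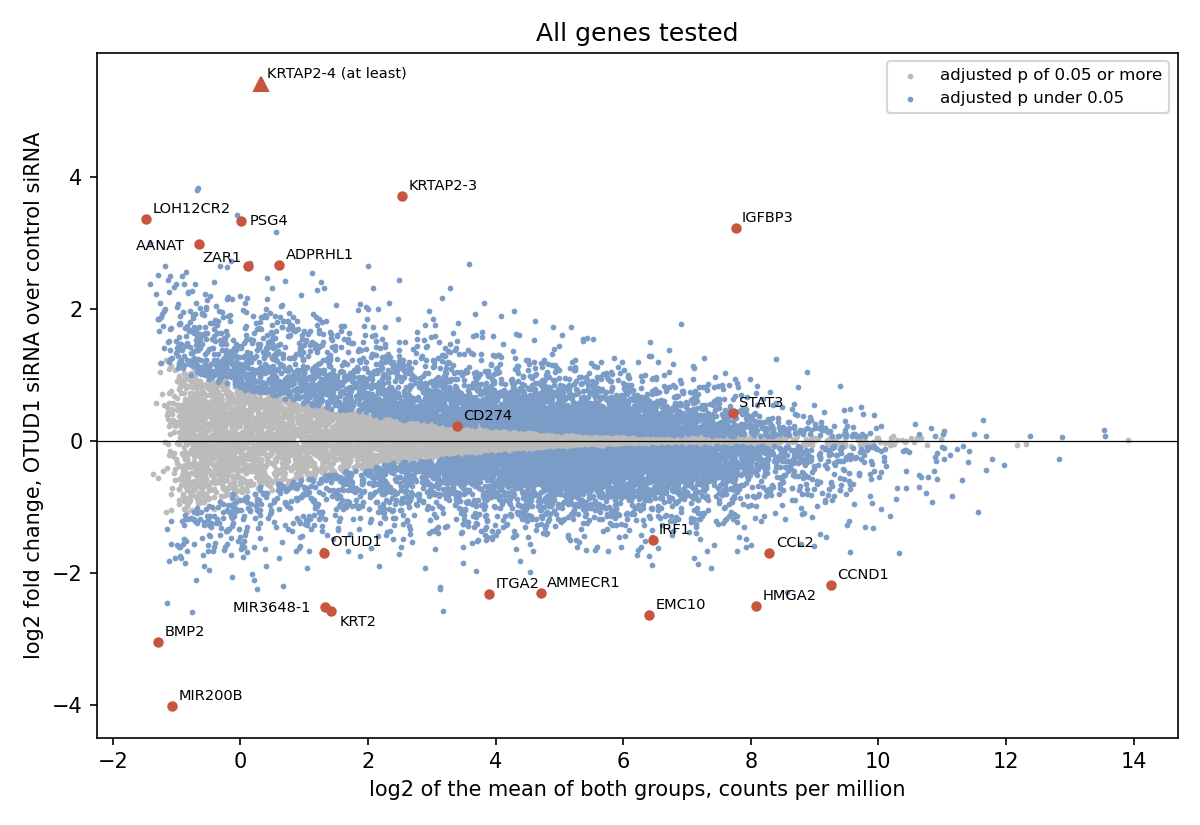
Log2 fold change, OTUD1 siRNA over control siRNA (vertical axis), against the log2 of the mean CPM of both groups (horizontal axis) for the genes tested with counts in both groups; blue points have an adjusted p under 0.05, grey points do not, and red points are named genes. IGFBP3 and HMGA2 combine high expression with log2 fold changes of 3.22 and -2.5, and the triangle marks KRTAP2-4 at its lower bound.

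Every tested gene of both cell-cycle lists fell. The 22 S phase genes had a median log2 fold change of -0.72, and the 24 genes of G2 and mitosis one of -0.66. RRM2, a subunit of ribonucleotide reductase, fell 2.72-fold from 95.1 ± 7.43 to 34.9 ± 1.59 CPM, and the replication licensing factor CDC6 fell 2.36-fold. The helicase subunits MCM3 and MCM7 fell 1.83-fold and 1.75-fold. KIF23, a kinesin of cytokinesis, fell 2.75-fold from 89.8 ± 3.6 to 32.6 ± 1.7 CPM, the proliferation marker MKI67 1.77-fold, cyclin B1 (CCNB1) 1.72-fold and topoisomerase TOP2A 1.6-fold. Adjusted over the list alone, the counts were again 22 of 22 and 24 of 24, while with library totals 21 S phase genes passed as lower. The 3′ UTR of RRM2 carries CAAACAA and those of CDC6, MCM3 and KIF23 the related 7-mer AAACAAA; those of the other members named here carry neither. The set test (camera) gave adjusted p = 2.59e-11 for S phase and 4.15e-12 for G2 and mitosis. For S phase the adjusted p was 0.0443 with an estimated correlation, and for G2 and mitosis the adjusted p was 0.0507 with an estimated correlation.

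Of 26 STAT3 target genes, 16 fell and 6 rose, STAT3 itself, a member of the list, being among those that rose. CCND1 went from 1001 ± 11.7 to 220.4 ± 4.7 CPM (log2 fold change -2.18, SE 0.03, edgeR adjusted p = 1.75e-29). The transcription factor genes IRF1 and FOSL1 fell 2.82-fold and 1.96-fold, while CEBPD rose 1.82-fold. The list's median was -0.22 (camera adjusted p = 0.0131, and adjusted p = 0.0945 with an estimated correlation). It was 0.102 after quantile normalization and 0.0512 with a minimum mean of 5 CPM. Adjusted over the list alone, 17 fell and 6 rose. CCND1 is also a driver of the entry into S phase.

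Immune checkpoint ligand genes and genes of antigen presentation moved in both directions. Of 11 checkpoint ligands tested, 5 fell and 2 rose, both over all genes and adjusted over the list alone. The costimulatory ligand TNFSF9 fell 1.81-fold, the TIGIT ligand PVR 1.51-fold and the phagocytosis checkpoint CD47 1.46-fold, while TNFRSF14 rose 1.36-fold and VSIR 1.26-fold. The list as a set did not pass (median -0.09, camera adjusted p = 0.516). Of 20 genes of MHC class I antigen presentation, 13 fell and 2 rose (14 and 2 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 0.00288, and adjusted p = 0.0789 with an estimated correlation; 0.123 after quantile normalization). The proteasome subunit PSMB10 fell 2.17-fold, and the chaperones CANX, CALR and TAPBP fell 1.85-fold, 1.65-fold and 1.63-fold. PSMB8 rose 1.17-fold and HLA-E 1.09-fold. CANX and CALR are general chaperones of the endoplasmic reticulum as well as members of this list. Of 4 T-cell attracting chemokine genes tested, CCL28 fell 1.79-fold and CX3CL1 1.15-fold, also when adjusted over the list alone, and the list did not pass (median -0.1, camera adjusted p = 0.722). CX3CL1 lost its call without OTUD1 siRNA replicate 1 (log2 fold change -0.18) and without OTUD1 siRNA replicate 2 (-0.13), after quantile normalization (-0.12), with library totals (-0.07), with limma without trend (-0.19) and with a minimum mean of 5 CPM (-0.15).

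Of 23 NF-kB target genes, 17 fell and 5 rose, with the same counts adjusted over the list alone. Their median was -0.51 (camera adjusted p = 6.8e-06, and adjusted p = 0.0591 with an estimated correlation). The chemokine CCL2 fell 3.26-fold, from 479 ± 29.1 to 147 ± 3.79 CPM (log2 fold change -1.7, SE 0.038, edgeR adjusted p = 2.1e-24). The inhibitor of apoptosis BIRC3 fell 2.79-fold, TNFAIP2 2.46-fold and the NF-kB inhibitor NFKBIA 2.28-fold. The chemokine CXCL2 rose 1.38-fold, and SOD2, whose symbol is shared by another row of the table, rose 1.3-fold. Of 27 type I interferon-stimulated genes, 9 fell and 5 rose, also when adjusted over the list alone. DDX60 fell 2.13-fold and the RNA sensor DDX58 1.88-fold, whereas IFI35 and IFITM3 rose 1.41-fold and 1.37-fold. This list did not pass (camera adjusted p = 0.788), and its median of 0.03 and its mean of -0.12 differ in sign.

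Other members of the OTU family of deubiquitinases changed too. With OTUD1 included, 10 of 13 fell and 2 rose, with the same counts adjusted over the list alone. OTULIN fell 1.62-fold, OTUD7B 1.51-fold and TNFAIP3 1.32-fold, while YOD1 rose 1.78-fold and OTUB2 1.12-fold. As a set the list did not pass (median -0.32, camera adjusted p = 0.0907; 0.0122 without a filter). OTUB2 lost its call without control siRNA replicate 2 (log2 fold change 0.13).

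Of 22 hypoxia and glycolysis genes, 15 fell and 4 rose (16 and 4 adjusted over the list alone). The median was -0.3 (camera adjusted p = 0.000541, and adjusted p = 0.0591 with an estimated correlation). The glucose transporter SLC2A1 fell 2.61-fold, NDRG1 2.28-fold, lactate dehydrogenase LDHA 1.92-fold and the oxygen sensor EGLN1 1.79-fold, whereas ADM rose 1.27-fold and VEGFA 1.25-fold. Of 20 NRF2 target genes, 14 fell and 1 rose, also when adjusted over the list alone. Their median was -0.39 (camera adjusted p = 5.31e-06, and adjusted p = 0.0507 with an estimated correlation). Heme oxygenase HMOX1 fell 2.04-fold, GCLM, of glutathione synthesis, 2.13-fold, the quinone reductase NQO1 1.91-fold and the thioredoxin reductase TXNRD1 1.78-fold, while malic enzyme ME1 rose 1.37-fold. Of 13 iron-handling genes, 7 fell and 3 rose (8 and 3 adjusted over the list alone), including the ferritin chains FTH1 and FTL, 1.49-fold and 1.28-fold lower, GPX4, 1.43-fold lower, and STEAP3, 1.4-fold lower. HFE rose 1.42-fold and the iron exporter SLC40A1 1.31-fold, and the list did not pass (median -0.13, camera adjusted p = 0.0939; 0.00958 without a filter).

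Of 16 epithelial-mesenchymal transition genes tested, 11 fell and 1 rose, also when adjusted over the list alone. The median was -0.35 (camera adjusted p = 0.00363, and adjusted p = 0.0793 with an estimated correlation; 0.0512 with a minimum mean of 5 CPM). The tight-junction gene CLDN1 fell 2.5-fold, N-cadherin (CDH2) 2.21-fold, vimentin (VIM) 1.42-fold and SPARC 1.24-fold, and EPCAM rose 1.1-fold. EPCAM lost its call without control siRNA replicate 1 (log2 fold change 0.14), control siRNA replicate 3 (0.11), OTUD1 siRNA replicate 2 (0.11) or OTUD1 siRNA replicate 3 (0.15), and also without a filter (0.13), with DESeq2 (0.14) and with limma without trend (0.13). Of 13 renal tubule markers, 7 fell and 4 rose, also when adjusted over the list alone. Keratins KRT8 and KRT18 fell 2.1-fold and 2.21-fold, the transcription factor PAX8 fell 1.57-fold, and KRT19 and GGT1 rose 1.33-fold and 1.32-fold. That list did not pass (median -0.34, camera adjusted p = 0.0893; 0.0242 with library totals and 2.27e-06 with camera on the DESeq2 Wald statistics). TGF-beta and YAP target genes split evenly, with 9 of 19 higher and 9 lower, also when adjusted over the list alone (median 0.19, camera adjusted p = 0.722). ANKRD1 rose 3.92-fold and CYR61 1.42-fold, while CTGF fell 2.13-fold and TEAD1 1.82-fold.

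The p53 target genes and those of the unfolded protein and integrated stress response went both ways. Of 22 p53 targets, 7 rose and 10 fell, also when adjusted over the list alone (median -0.09, camera adjusted p = 0.877). TP53I3 rose 1.97-fold and FDXR 1.8-fold, whereas the death receptor FAS fell 1.79-fold and the cyclin-dependent kinase inhibitor CDKN1A 1.36-fold. Of 22 stress-response genes, 8 rose and 8 fell, also when adjusted over the list alone (median -0.01, camera adjusted p = 0.925). TRIB3 rose 1.56-fold and SESN2 1.25-fold, while the cystine transporter SLC7A11 fell 2.19-fold, HERPUD1 1.41-fold and PDIA4 1.23-fold. Of 22 cholesterol synthesis genes, 10 rose and 5 fell, also when adjusted over the list alone (median 0.07, camera adjusted p = 0.419). INSIG1 rose 2.06-fold and LSS 1.32-fold.

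Markers of other cell types and of RNA composition gave no common direction under TMM scaling. Of 3 leukocyte markers tested, CD8A was 3.7-fold higher (95% counting interval 1.76 to 8.68) from 9 counts over the control libraries and 39 over the OTUD1 siRNA libraries, and it was the 1 called both over all genes and adjusted over the list alone (median 0.15, camera adjusted p = 0.838). CD8A lost its call after quantile normalization (log2 fold change 0.36, adjusted p = 0.0707). Of 5 fibroblast and endothelial markers, ACTA2 rose 2.47-fold and PDGFRB 1.74-fold, while THY1 fell 2.1-fold and ENG 1.55-fold. Adjusted over the list alone, 3 rose and 2 fell (median 0.37, camera adjusted p = 0.925). Of 13 mitochondrially encoded mRNAs, 6 rose and 3 fell, also when adjusted over the list alone (median 0.06, camera adjusted p = 0.618). MT-ND6 and MT-ND5 rose 1.16-fold and 1.14-fold, and MT-ND1 and MT-ATP6 fell 1.16-fold and 1.11-fold under TMM but had log2 fold changes of 0.03 and 0.09 after quantile normalization. Of 32 cytosolic ribosomal protein genes, 7 rose and 4 fell (6 and 4 adjusted over the list alone; median 0, camera adjusted p = 0.773). RPL11 rose 1.22-fold and RPL13 1.11-fold. RPL3 fell 1.08-fold under TMM but had log2 fold changes of 0.08 after quantile normalization and 0.02 with library totals. The ribosomal and mitochondrial lists passed as higher after quantile normalization (camera adjusted p = 1.86e-09 and 0.00171) and with library totals (0.00292 and 0.0358).

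**Figure D3:**
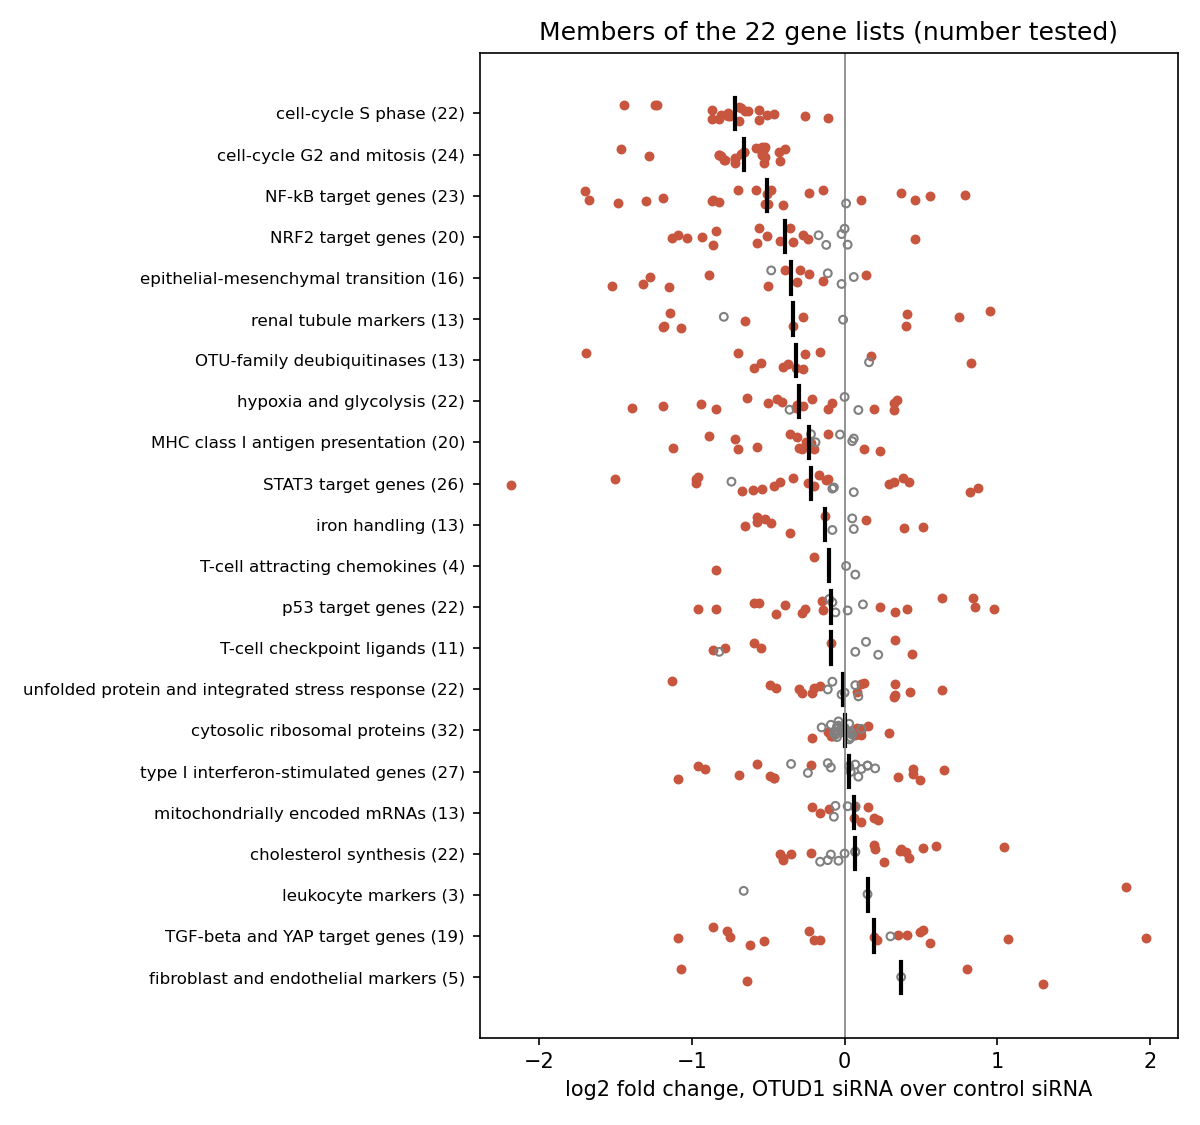
Log2 fold change, OTUD1 siRNA over control siRNA (horizontal axis), of each tested member of the 22 gene lists (vertical axis, with the number tested); filled points have an adjusted p under 0.05 over all genes, open points do not, and black bars are list medians. All members of the S phase and the G2 and mitosis lists lie below 0, with medians of -0.72 and -0.66.

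Of the 22 lists, 8 passed the set test as lower and 0 as higher with TMM scaling and camera, and 1 as lower with an estimated correlation. In the first test the smallest unadjusted p of a list moving up was 0.229, while fry, quantile normalization and library totals each gave 2 higher lists. Scaling by library totals in place of TMM raised the median log2 fold change of all genes from 0.006 to 0.134 and the share of higher genes among the calls from 48.4% to 64.2%, so directions of small changes hold relative to TMM scaling. Among the other list members named here, CAAACAA occurs in the 3′ UTRs of CALR, CCL28, OTUD7B, LDHA, NDRG1, EGLN1, SLC7A11, CTGF, CLDN1, CDH2 and PAX8, which fell, and of TRIB3, CYR61 and HFE, which rose. AAACAAA without it occurs in those of DDX58, DDX60, CANX, BIRC3, OTULIN, TXNRD1, FAS and CDKN1A, which fell, and of VSIR, INSIG1, SLC40A1, CD8A and RPL13, which rose. The groups did not overlap in 9827 genes (64.5%). Chance gives 10% for a single gene, but genes are not independent of each other, so this share is no test of chance.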

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

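DESeq2, limma on log2 CPM and limma without trend, library totals, the filter at a mean of at least 5 CPM, robust dispersion and the test against a 1.5-fold change were chosen after seeing the data. The planned settings on FPKM (other pseudocounts, rescaling to TPM, variance models on FPKM and a minimum of 5 FPKM) were not run, because the table holds counts. OTUD1 and STAT3 kept their direction and side of the threshold under the alternatives that gave them a value, as did the S phase list. OTUD1 is below the filter at 5 CPM, and the test against a 1.5-fold change was run for gene counts only. Leaving out 1 replicate at a time gave log2 fold changes of -1.81 to -1.5 for OTUD1, 0.4 to 0.43 for STAT3 and 0.16 to 0.29 for CD274, with 4038 to 4337 genes higher and 4443 to 4624 lower. CD274 passed the threshold without OTUD1 siRNA replicate 3 (0.29), with library totals (0.35) and with the filter at 5 CPM (0.27). With the filter at 5 CPM fewer genes were tested, but the CD274 log2 fold change also moved, from 0.22 to 0.27. With library totals the median log2 fold change of all genes rose as well, from 0.006 to 0.134. The cause was not tested for any of these settings.

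The number of genes higher and lower by at least 1 on the log2 scale was 225 and 298 after quantile normalization, 268 and 313 with limma on log2(CPM + 1), 266 and 313 with limma without trend, and 254 and 282 with the filter at 5 CPM, against 844 and 538. The pseudocount shrinks the changes of genes with few counts, and the filter removes such genes. Tested against a 1.5-fold change, 840 genes were higher and 939 lower. DESeq2 called 4043 higher and 4348 lower. No clear pairing of the samples by replicate number was seen. Correlations of deviations within a number were 0.028, 0.13 and -0.0025, and not every sample correlated best with its own number. The fit with the replicate block made 9275 calls in place of 9206. With 3 libraries per group, these values cannot exclude a shared culture or day.

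For the STAT3 target list the camera adjusted p was 0.102 after quantile normalization, 0.0512 with the filter at 5 CPM and 0.0945 with an estimated correlation, and for G2 and mitosis it was 0.0507 with an estimated correlation. With an estimated correlation, 1 list was lower. Without a filter 10 were lower, with the iron-handling (0.00958) and OTU-family lists (0.0122) added. By fry, which does not compare a list with other genes, 16 lists were lower and 2 higher, the checkpoint ligands had an adjusted p of 5.56e-05, and the fibroblast and endothelial list turned to lower (0.00797). Quantile normalization and library totals each gave 2 higher lists, the ribosomal and the mitochondrial mRNAs. The renal tubule list passed as lower with library totals (0.0242) and with DESeq2 (2.27e-06, camera on its Wald statistics), each with 9 lower lists. Among the genes reported, the log2 fold changes that turned sign were those of MT-ND1 (0.03), MT-ATP6 (0.09) and RPL3 (0.08) after quantile normalization, and RPL3 (0.02) with library totals; the cause was not tested. Among the other named genes and lists, 2236 values under alternatives kept their direction and side of the threshold, 27 no longer passed and 16 passed anew. Besides those that turned sign, reported genes that lost their call under at least 1 alternative were EPCAM, CX3CL1, OTUB2, CD8A, HLA-E and RPL13. Depth limits the values of genes with few counts, OTUD1 among them, most.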

Other observations

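The tests of library scaling for the cell-cycle lists, of base composition and of reverse complements, of the amount of genomic DNA and of other splits were chosen only after the results they bear on had been seen. Among long non-coding RNAs that passed the test, more rose than fell after OTUD1 siRNA. Of 547 lincRNA genes tested, 261 rose and 30 fell (median log2 fold change 0.56), and of 676 antisense genes, 257 rose and 52 fell (0.46), against 3671 higher and 4502 lower among 12745 protein-coding genes (-0.03). Summed lincRNA levels were 2218 to 2239 CPM in the control libraries and 2971 to 3013 CPM in the OTUD1 siRNA libraries.

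A short sequence was more frequent in the 3′ UTRs of lower genes than of higher genes. Of all 7-mers, AAACAAA was tied most strongly to lower log2 fold changes (t = -15.45, median -0.18 in 3704 carriers and 0.02 in other genes), followed by CAAACAA (t = -14.92). Unlike these in sequence, CAGTTGT (t = -7.43), AGTTGTA (t = -5.85) and AGTTGTT (t = -5.62) were also tied to lower log2 fold changes. CAGTTGT and AGTTGTT occur in the OTUD1 mRNA, and AGTTGTA does not. Genes with the joined 8-mer CAAACAAA had a median of -0.31. Those with CAAACAA but not the 8-mer, some of which also carry a separate AAACAAA, had -0.19. The median was -0.13 with AAACAAA but no CAAACAA, -0.03 with the hexamer AAACAA but neither 7-mer, and 0.04 with none. These medians and the shares that follow are not adjusted for 3′ UTR length, whose median was 3177, 2797, 2372, 1591 and 582 bases in the same order. Either 7-mer occurred in 66.3% of the 445 genes lower by at least 1 on the log2 scale with a 3′ UTR searched, in 45.6% of all lower genes and in 22.2% of higher genes. CAAACAA occurs in the OTUD1 mRNA at chromosome 10, 23440804 to 23440810, in the coding sequence and as part of the 8-mer, and at 23441984 to 23441990, in the 3′ UTR. The 7-mer most strongly tied to higher log2 fold changes was GGAGAAA (t = 7.89, effect 0.104), which does not occur in the OTUD1 mRNA. Similar 7-mers followed. CGGAGAA (effect 0.194, 279 carriers) and CGGAGAT (0.207, 210 carriers) are absent from the OTUD1 mRNA, and TGGAGAA (0.078) occurs in it. Absence from the OTUD1 mRNA says nothing about effects of the control siRNA, which were not tested.

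A candidate explanation for the lower genes is silencing by the OTUD1 siRNA through matches to its seed, the short guide segment that pairs with 3′ UTRs. The top 7-mer does occur in the OTUD1 mRNA, as this explanation needs and as 14.7% of all 7-mers do. The medians of carriers and other genes differed by -0.21, also as needed. That 7-mer was picked from these same fold changes, however, so the lower median followed from the choice and lends no support. A base composition rich in A is argued against only within the 6756 genes without AAACAA, whose 3′ UTRs were shorter (median 582 bases). There, the 5 other orders of the bases of AAACAAA that do not contain AAACAA had a mean effect of -0.0089 on the log2 scale (-0.077 to 0.032). This was 4.57% of the -0.195 for AAACAAA over all genes. The 19 of CAAACAA had a mean effect of 0.0075 (-0.058 to 0.047), against -0.224 over all genes. Over all genes, AAAACAA, which contains AAACAA and is absent from the OTUD1 mRNA, had an effect of -0.165. The orders AACAAAA, AAAAACA and ACAAAAA had effects of -0.131, -0.076 and -0.07 over all genes. For genes with AAACAA, composition therefore stays open. The reverse complements TTTGTTT and TTGTTTG had effects of -0.043 and -0.028. The siRNA sequence was not used here, so seed matching stays a hypothesis. Loss of OTUD1 protein stays an open, untested cause for the 2406 lower genes without either 7-mer and for the 2020 that carry either.

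For the fall of the cell-cycle lists, a factor per library shifts all genes alike and tests nothing, but quantile normalization, which can move the lists against other genes, left their medians -0.66 (S phase) and -0.57 (G2 and mitosis) from the median of all genes. Direct seed matching as the whole cause is argued against: the 38 members without AAACAAA had a median log2 fold change of -0.66 (quartiles -0.78 and -0.53), all of them lower, as were the 32 without AAACAA (median -0.65). The 6 S phase members with either 7-mer had a median of -1.05, against -0.66 for the 16 without. For G2 and mitosis, the 4 with either 7-mer had -0.72, against -0.62 for the 20 without. Seed matching may therefore add to the fall. The difference rests on few genes, was not adjusted for 3′ UTR length and was not tested. What stays open is an effect of OTUD1 loss on proliferation, or one downstream of other genes the siRNA may lower. No test here bears on which, since no rescue with OTUD1 is among the samples analysed.

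For the higher non-coding RNAs, genomic DNA was weighed first: olfactory receptor genes were 1.81 times as high in the OTUD1 siRNA libraries, from 13 to 23 counts per control library and 29 to 33 per OTUD1 siRNA library, which goes with more DNA. The amount is far too small, since at the upper 95% bound DNA would give 6.22 of the 1344 CPM by which lincRNA and antisense genes rose, or 0.463%. Bias from GC content or transcript length is argued against. The difference from protein-coding genes of 0.52 (95% bootstrap interval 0.48 to 0.57) kept 88.9% of its size after both trends were removed (0.47, 0.41 to 0.52). The bootstrap intervals come from resampling genes and hold no spread between libraries. Matched on mean expression it kept 69.6% (0.36, 0.31 to 0.41), so low expression may account for part of it. A biological effect of OTUD1 siRNA stays open, and antisense counts also depend on a strand setting that is not given in the sources used here.

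With 3 libraries against 3, the 10 splits are too few for a share under 0.05. The real split, 1 of the 10, gave 9206 called genes, 1382 genes changed by at least 1 on the log2 scale and 8 lists past the threshold. The highest among the other splits were 0 genes, 0 genes and 6 lists with edgeR and camera. Each of those splits mixes both conditions in each group, so the difference between conditions widens the spread within groups. Few calls there follow from this design, and the contrast with them lends the real split no support. In those splits 82 to 124 genes had an unadjusted p under 0.05, and DESeq2 called at most 2.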
